A study of Mus musculus with 2 samples.

How the data were processed

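RNA levels were measured on Affymetrix mouse genome GeneChips in ovaries of 2 genotypes, wild type and progesterone receptor (PR) knockout, with 1 array per genotype. Per the labels' protocols, RNA was isolated with Trizol and cleaned on Qiagen columns. Biotin-labelled antisense RNA was then made from 100 ng of total RNA with an Affymetrix kit that primes at the 3′ end. Signals are therefore read mostly near the 3′ end of transcripts. How many mice or ovaries went into each RNA sample is not given in the sources used here.

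The deposited table holds 1 linear intensity per probe set and array. Per the submitters' processing notes, the authors computed these intensities with MAS5 and Affymetrix Expression Console version 1. On both arrays the mean signal after trimming 2% of the 45101 probe sets at each end was 150, so each array had been scaled by a single factor to that target. No detection calls or probe-level files were used here. MAS5 corrects each perfect-match probe with a mismatch probe, which makes the lowest signals noisy, and it applies no correction for trends with intensity.

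Signals were used as deposited and taken to log2. The 64 control probe sets were set aside, which left 45037. Of these, 34945 carried exactly 1 gene symbol in the platform annotation, 932 carried several and 9160 carried none. The gene IDs of 34741 of the single-symbol probe sets were found in the RefSeq gene table of GRCm38.p6, and 0 symbols needed updating. The deposited values name no genome build, so the RefSeq table served only for names and for which genes neighbour Pgr, and positions are not reported. Probe sets with several symbols or none stayed out of the gene comparison. Each of the 18193 genes was represented by its probe set with the highest mean log2 signal over both arrays.

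The floor was each array's median signal over probe sets that are not controls, 36.2 on the wild-type and 37.95 on the knockout array. A gene counted as measured if its probe set reached the floor on at least 1 array, which held for 11316 genes. Signals under the floor were set to the floor, so a fold against a floored array is a lower bound and is written as "at least". Folds against a signal that passed the floor but lay no higher than the Pgr signals are written the same way, since such a signal is not clearly above background. Of the measured genes, 10633 were at or above the floor on both arrays and 683 on 1 array only.

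With 1 array per genotype there are no replicates, no test across animals was possible, and no p-value is given. Values are single measurements, and the number of arrays limits their precision. A difference between the arrays can come from genotype, from the individual animals, or from the RNA preparation and hybridization. The labels give no batch, and any batch would coincide with genotype. The one spread that the arrays allow is between probe sets of the same gene. Over 4771 genes with 2 or more probe sets measured on both arrays, the within-gene SD of the log2 difference was 0.25 (root mean square), or 1.19-fold. This covers probe and transcript-form differences and leaves out the spread between animals.

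Before the data were examined, 33 gene lists were fixed from general knowledge of ovulation, of ovarian cell types and of tissues that a dissected ovary can carry. They hold 555 genes, of which 502 had a single-symbol probe set and 427 were measured. The lists not described in the results proper, such as neighbours of Pgr, sex check, steroid receptors and circadian clock genes, are given with the other observations. For each list with at least 5 measured members, the median log2 difference (knockout minus wild type) was placed among the medians of 10000 random lists of the same size. The random lists were matched on mean signal in 20 bins. The percentile describes these 2 arrays and is not a p-value for genotype. Lists overlap: 13 of the 18 steroid synthesis genes, 6 of 10 theca, 8 of 11 luteal, 5 of 17 granulosa and 1 of 12 surface epithelium genes are also in another list. With 30 lists that had enough members, about 1.5 would fall outside the central 95% of random lists if no list stood apart and members varied independently. Genes of 1 list can vary together between any 2 samples, which random lists leave out, so more lists than this may fall outside without an effect of genotype.

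Genes were named by a rule fixed at the same time. It takes Pgr, then the 12 largest differences in each direction among genes measured on both arrays, then the 4 brightest genes in each direction measured on 1 array and at least 2-fold above the other array's floor. Other measured probe sets of such a gene had to differ in the same direction, and placeholder symbols were not named. From each list the 4 largest differences were added, and from the receptor-dependent list each measured member.

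The calculation was tested on simulated data drawn from the signals of these 2 arrays, with 200 genes changed by known amounts among 11233 measured genes. Noise was drawn from probe sets that differed by under 2-fold, so the simulation tests recovery and says nothing about how many unchanged genes pass the threshold by chance. At the 2-fold threshold it called 96% of genes raised by 1.5 on the log2 scale and 84% of genes lowered by as much. It called 100% of genes raised by 3 and 86% of genes lowered by 3, since the floor caps how far a dim gene can go down. Of 200 lists of unchanged genes, 5.5% fell outside the central 95% of random lists. These lists were drawn at random with independent noise, so this share follows from the construction and does not cover genes that vary together. The simulated noise does not stand for the spread between animals.

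Alternatives fixed in advance were median centring, quantile normalization, removal of a loess trend on mean signal (span 0.3), floors at the 25th and 70th percentiles, no floor, an offset of 50 before log2, the mean over a gene's probe sets, leaving out probe sets that can match several transcripts, thresholds of 1.5-fold and 3-fold, and a 10% trimmed mean for lists. Leaving out members shared with the receptor-dependent list was added after seeing the data. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6.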

Results

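The study compared gene expression in ovaries of wild-type mice and of mice lacking the progesterone receptor, a hormone-activated transcription factor (gene Pgr), around the time of ovulation. Immature C57BL/6 mice aged 24 to 28 days received 5 IU of pregnant mare serum gonadotropin (PMSG), which drives follicle growth. After 48 h they received 5 IU of human chorionic gonadotropin (hCG), which acts on the luteinizing hormone receptor and triggers ovulation. Ovaries were taken 11 h after hCG, and 1 wild-type and 1 PR knockout RNA sample were each hybridized to 1 array. There are no replicates, so each value below is a single measurement and no difference was tested against the spread between animals. The median signal over probe sets other than controls, used as the floor for a measurable signal, was 36.2 on the wild-type and 37.95 on the knockout array. Across probe sets at or above the floor on both arrays, log2 signals correlated with r = 0.97, a value across probe sets, which are not independent replicates.

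The targeted gene was read by 3 probe sets, and their signals were close to or under the floor in both genotypes. The brightest of them gave 36.5 in the wild-type and 42.8 in the knockout ovary, close to the floors. The others gave 2.97 and 3.64, and 1.03 and 21.1, in the same order. Pgr transcript was thus not measurably above background in the wild-type ovary at this time, and the array gives no check of the genotype labels. The labels do not give the disrupted part of the gene, so a 3′ probe set need not respond to the disruption.

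The large differences between the genotypes lay mostly towards lower signal in the knockout ovary, with Edn2, Ptgs2, Il6 and Ereg among them. Of 11316 measured genes, 195 were at least 2-fold lower and 130 at least 2-fold higher in the knockout. This asymmetry held from 2-fold upwards and turned at a 1.5-fold threshold, where 740 genes were higher and 538 lower in place of the genes at least 2-fold higher in the knockout array and the genes at least 2-fold lower in the knockout array. It grew with size: 70 genes were at least 3-fold lower against 10 higher, 39 at least 4-fold lower against 4 higher, and 9 at least 8-fold lower against 0 higher. Genes that were lower were also brighter, with a median of 434 on their brighter array against 140 for the genes that were higher. The median difference over measured genes was 0.06 on the log2 scale, with quartiles of -0.14 and 0.27. It was 0.11 in the dimmest and -0.05 in the brightest of 10 bins of mean signal. The counts at 1.5-fold were taken without rescaling, so this trend with signal may add to the genes counted as higher there. The split between higher and lower depended on scaling: it was 97 against 219 after median centring, 93 against 214 after quantile normalization and 87 against 230 after removal of the loess trend. Floors, offset and threshold moved both counts by more than 1.5 times.

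**Figure D1:**
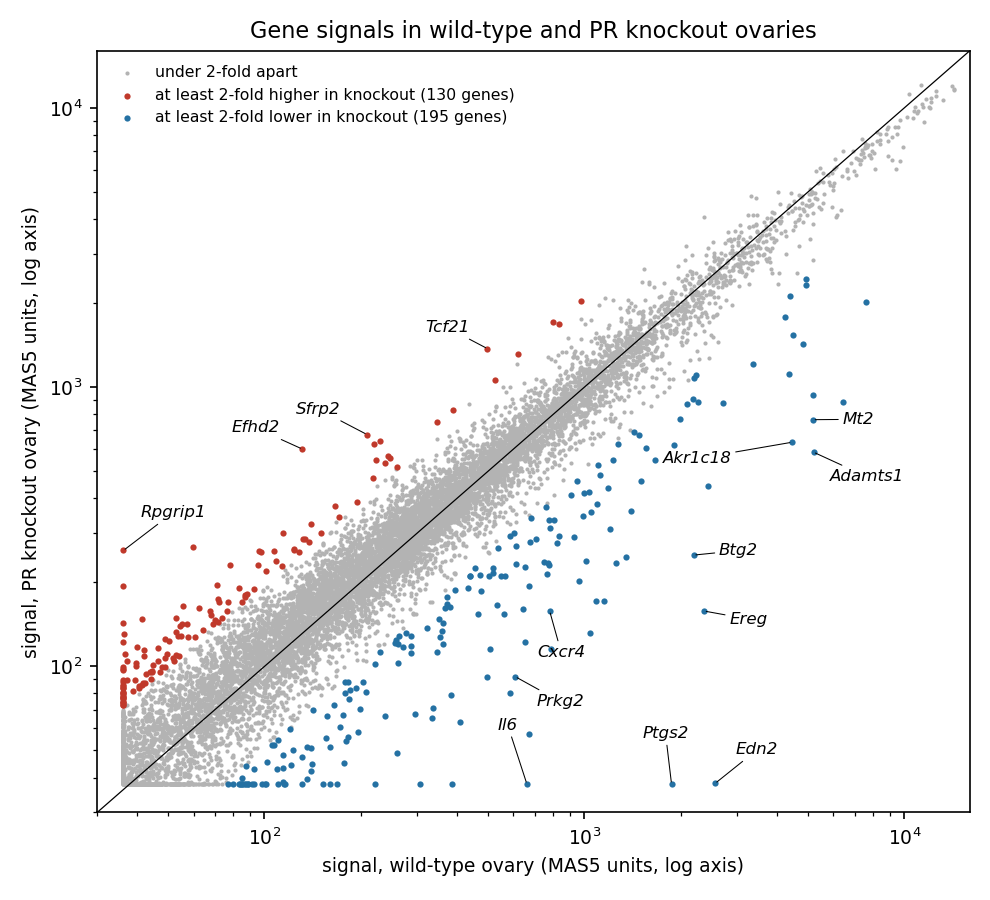
Signal of each measured gene in the wild-type ovary (horizontal axis, MAS5 units, log scale) against the PR knockout ovary (vertical axis, same units, log scale), 1 array per genotype, with signals under an array's floor drawn at the floor. The 195 genes at least 2-fold lower in the knockout (blue) reach much farther from the line of equality than the 130 genes at least 2-fold higher (red).

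Among the largest differences on the arrays was that in Edn2, which encodes the vasoconstrictor peptide endothelin-2. Its signal was 2562 in the wild-type and 38.1 in the knockout ovary, at least 67.2-fold lower, since the knockout signal was at the floor. Ptgs2, the inducible prostaglandin synthase, had a signal of 1871 in the wild type and was under the floor in the knockout, at least 49.3-fold lower, and its other measured probe set gave a log2 difference of -3.65. Il6, an inflammatory cytokine, was at least 17.4-fold lower and the EGF-family ligand gene Ereg had a log2 difference of -3.91. Epgn, which encodes another EGF-family ligand, was at least 8.08-fold lower, and Ldhd, a mitochondrial lactate dehydrogenase, at least 10.1-fold lower, with -1.78 on the log2 scale in its other measured probe set. The other genes with the largest differences towards lower signal were the transcription factor genes Egr3 (11.8-fold) and Junb (6.81-fold) and the growth-inhibitory gene Btg2 (8.78-fold). Among feedback inhibitors of growth factor and cytokine signalling, Dusp5 was 7.26-fold, Errfi1 7.25-fold and Socs3 6.68-fold lower, the last with probe sets from -2.74 to -1.66 on the log2 scale. The protease gene Adamts1 was 8.89-fold lower, tissue factor (F3) 7.89-fold, the metal-binding protein gene Mt2 6.79-fold, and Akr1c18, whose product inactivates progesterone, 7.01-fold.

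Genes that were higher in the knockout ovary were dimmer and differed less. Efhd2, a calcium-binding protein gene, was 4.57-fold higher by its brightest probe set, but its other measured probe set gave a log2 difference of 0.63. Gdpd3, a phospholipid-metabolizing enzyme gene, was 4.48-fold higher, the protease inhibitor gene A2m at least 3.59-fold and Colgalt2, a collagen-glycosylating enzyme gene, at least 3.55-fold. Sfrp2, which encodes a secreted modulator of Wnt signalling, was 3.24-fold higher with signals of 209 and 676. Ccrl2 was 2.94-fold, Pdpn 2.84-fold, Aox1 2.83-fold and Kcnk3 2.81-fold higher, and Skida1, Prodh and Rgs13, whose wild-type signals were close to the floor, at least 3.03-fold, 2.95-fold and 2.80-fold. The membrane protein gene Pdpn and the potassium channel gene Kcnk3 were the brightest of these in the wild type, at 220 and 229. With the 70th-percentile floor A2m, Colgalt2, Ccrl2, Aox1, Kcnj11 and Hddc3 were under 2-fold. Skida1, Prodh, Rgs13 and Abcb10 lay under that floor on both arrays and were not measured there. With the offset Skida1, Prodh, Aox1, Rgs13 and Abcb10 were under 2-fold. Abcb10 was also under 2-fold with the mean over its probe sets, the other of which gave 0.52 on the log2 scale. The 3 measured probe sets of Kcnk3 ranged from 0.98 to 1.49. Among genes under the floor in the wild type, Rpgrip1 was at least 7.17-fold higher, the potassium channel gene Kcnj11 at least 5.34-fold, Hddc3 at least 3.94-fold and Abcb10 at least 2.74-fold. The wild-type signals of these 4 genes, between 28.4 and 34.8, lay under the floor.

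Whether genes reported to depend on the receptor in ovulating follicles differ here was asked with a list of 13, all of them measured. The list was drawn from general knowledge of earlier work on such mice, and whether that work used these arrays is not given in the sources used here, so its direction is not independent evidence. Of the 13 genes, 12 had lower signal in the knockout, 7 of them by at least 2-fold, and 0 were at least 2-fold higher. The median log2 difference was -2.01, below the central 95% of matched random lists (-0.17 to 0.21). This median is the value of Snap25, whose knockout signal was set to the floor, and the next member towards 0 was Hif1a at -0.78. With the 70th-percentile floor the median of the list was -1.38. Besides Edn2, Il6 and Adamts1, Prkg2, a cGMP-dependent protein kinase gene, was 6.63-fold lower, with 3 measured probe sets from -2.73 to -1.64 on the log2 scale. The chemokine receptor gene Cxcr4 was 4.93-fold lower, the transcription factor gene Zbtb16 4.37-fold and the exocytosis gene Snap25 at least 4.03-fold, a bound that was under 2-fold with the 70th-percentile floor. Zbtb16 was less clear than its brightest probe set, since its 3 measured probe sets ranged from -2.13 to -0.47 on the log2 scale. Smaller differences were seen for the hypoxia-inducible factor genes Hif1a (1.71-fold lower) and Epas1 (1.35-fold lower, and -0.95 on the log2 scale in its other measured probe set), while their partner gene Arnt was 1.44-fold higher by its brightest probe set, with probe sets from -0.16 to 0.53 on the log2 scale. Ctsl, which encodes a lysosomal protease, was 1.56-fold lower and the neuropeptide gene Adcyap1 1.57-fold lower at a dim signal of 72.7 and 46.4. Pparg, a nuclear receptor gene, was 1.28-fold lower. With the mean over each gene's probe sets, the median log2 difference of the list progesterone receptor-dependent genes of the ovulatory follicle was -1.11.

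**Figure D2:**
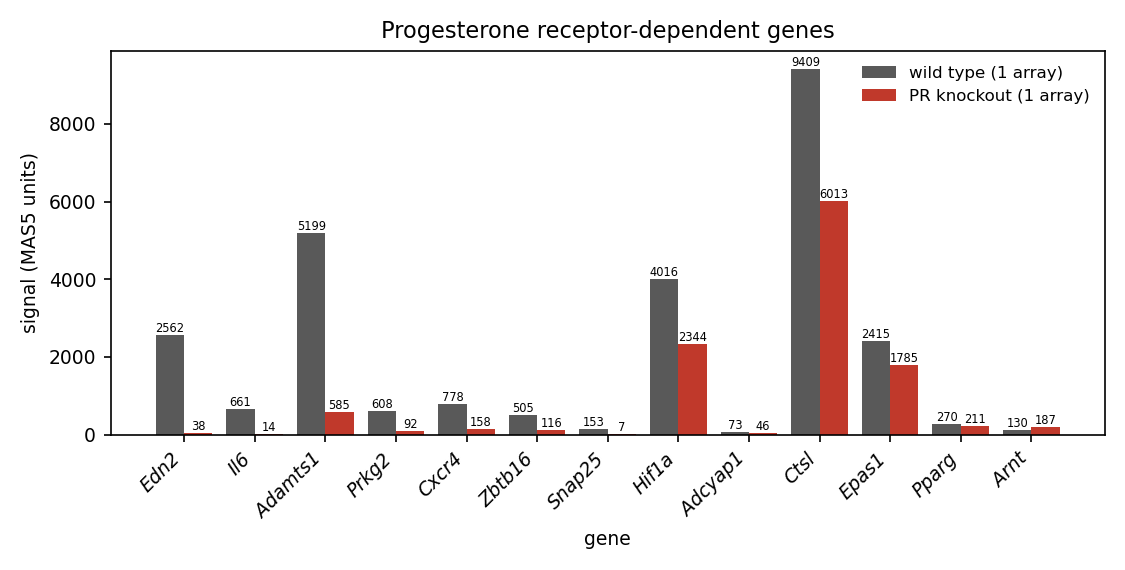
Signals (vertical axis, MAS5 units, linear) of the 13 genes of the receptor-dependent list (horizontal axis) in the wild-type (grey) and PR knockout (red) ovary, 1 array each and no error bars. The knockout bar is the lower one for 12 genes, with Edn2 at 38.1 against 2562, and the higher one for Arnt.

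Genes of cumulus expansion were mostly lower in the knockout ovary, 11 of 13 measured. In this process the cells around the oocyte build a hyaluronan matrix in response to EGF-like ligands. The other members were higher in the knockout on the log2 scale, Ptger2 by 0.54 and Gja1 by 0.018. The Gja1 value is from its brightest probe set, the lowest of 6 measured. Of 13 measured, 7 were at least 2-fold lower and 0 at least 2-fold higher, with a median log2 difference of -1.23 against a random range of -0.15 to 0.23. This median is the value of Has2, with a signal of 88.7 in the wild type and under the floor in the knockout. The other measured probe set of Has2 gave -0.45 on the log2 scale. After Ptgs2 and Ereg, the largest differences were in the matrix-linking genes Tnfaip6 (4.84-fold lower, 383 to 79.2) and Ptx3 (3.94-fold lower, but under 2-fold with the 70th-percentile floor). With that floor the median log2 difference of the list cumulus expansion and EGF-like factors was -0.64.

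Transcription factors and regulators that luteinizing hormone induces were likewise mostly lower, 19 of 21 measured. Nrip1 was 1.66-fold higher by its brightest probe set, with probe sets from -0.50 to 1.22 on the log2 scale, and Sgk1 1.05-fold higher. Of 21 measured genes, 9 were at least 2-fold lower and 0 at least 2-fold higher, and the median was -0.74 against a random range of -0.14 to 0.14. Btg2 and Junb differed most. They were followed by the immediate-early transcription factor gene Egr1, 5.56-fold lower at 5195 and 935, and the orphan nuclear receptor gene Nr4a3, 5.28-fold lower. In these 3 lists the position below random lists held under the 3 scaling alternatives.

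Among cytokine and chemokine genes, 12 of 13 measured had lower signal in the knockout, 5 by at least 2-fold, and the median was -0.59 (random range -0.13 to 0.24). This median is the value of Cxcl12 by its brightest probe set, while its other measured probe set gave 0.72 on the log2 scale. The probe sets of Cxcl1 ran from -0.57 to 0.12. The list holds 26 genes. Il6, Il11, Il1b, Ccl2 and Tlr4 were under the floor in the knockout and counted as measured through the wild type only. Of these Il1b, Ccl2 and Tlr4 were dim there too (47.6, 46.9 and 42.8), so their direction rests largely on the floor. Il6, Socs3 and Cxcr4 led, and Il11 was at least 2.90-fold lower, though it lay under the 70th-percentile floor on both arrays. Over the alternatives the median log2 difference of the list cytokines and chemokines ran from -1.29 with the 70th-percentile floor to -0.33 with the mean over probe sets. Without the 2 members shared with the receptor-dependent list, the median of the other 11 was -0.41, at percentile 0.01 of random lists. Extracellular proteolysis genes had a median of -0.25 (-0.13 to 0.14), with 3 of 20 at least 2-fold lower. These were Adamts1, Adamts4 (3.36-fold) and Adam8 (2.82-fold), while Mmp2, a gelatin-degrading metalloprotease gene, was 1.99-fold higher. Adam8 was under 2-fold with the 70th-percentile floor. Over the alternatives the median log2 difference of the list extracellular proteolysis ran from -0.65 with no floor to -0.13 with the mean over probe sets. Without the 2 shared members, the median of 18 was -0.16, at percentile 0.69.

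Other pathways of ovulation had medians inside the range of random lists. The prostaglandin list had a median of 0.16 (percentile 84.5) despite Ptgs2: its mean was -0.40, and 1 of 14 members was at least 2-fold lower. Its next members were the prostaglandin transporter gene Slco2a1 (1.99-fold lower, with probe sets from -0.99 to -0.12 on the log2 scale), Cbr2 (at least 1.87-fold higher) and the receptor gene Ptger4 (1.74-fold lower). Vascular and contractile signalling peptides had a median of 0.06 (percentile 39.4), a mean of -0.47 and 2 members at least 2-fold lower, Edn2 and Prkg2. On the other side, the angiotensin receptor gene Agtr1a was 2.07-fold higher, but under 2-fold after any of the 3 rescalings, and the endothelin receptor gene Ednrb was 1.96-fold higher, with probe sets from 0.30 to 0.97 on the log2 scale. The secretion list had a median of 0.00 (percentile 25.3) and a mean of -0.29, with Snap25 the 1 member of 8 at least 2-fold lower and Chgb, a secretory granule protein gene, 1.91-fold lower. The signs of the vascular and secretion medians turned under at least 1 rescaling.

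Hypoxia and glycolysis genes had a median of -0.28 (random range -0.11 to 0.16), with 18 of 23 lower and 2 of them by at least 2-fold. The transcriptional repressor gene Bhlhe40 was 2.94-fold lower and Ndrg1 2.27-fold lower, the latter under 2-fold with the mean over its probe sets. The glucose transporter gene Slc2a1 was 1.95-fold lower and the glycolytic regulator gene Pfkfb3 1.61-fold lower. Heat shock and stress genes had a median of -0.45 (-0.18 to 0.08), with 12 of 16 lower. The metallothionein genes led, with Mt2 6.79-fold and Mt1 3.77-fold lower, followed by the chaperone genes Hspa1a (1.94-fold) and Hspa1b (1.85-fold).

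Steroid hormone synthesis genes had a median of -0.07 over 12 genes (percentile 40.6) and a mean of -0.41, and 2 were at least 2-fold lower. As a trimmed mean, the median log2 difference of the list steroid hormone synthesis went to -0.27. These were Akr1c18 and the estrogen sulfotransferase gene Sult1e1, at least 3.04-fold lower. Star, which encodes the cholesterol carrier of the first step of steroid synthesis, was 1.47-fold lower, and Hsd17b1, an enzyme of estradiol synthesis, 1.54-fold higher. Of 19 cholesterol synthesis and uptake genes measured, 17 had lower signal in the knockout and 0 by 2-fold, with a median of -0.26 (-0.16 to 0.10), or 1.20-fold. Mvk was 1.62-fold (its other measured probe set gave -0.04 on the log2 scale), Sqle 1.51-fold, Insig1 1.46-fold and Mvd 1.46-fold lower.

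Cell type markers were compared to describe the makeup of the samples. Granulosa cell genes of growing follicles were higher in the knockout as a group, with 13 of 16 higher, 0 by 2-fold, and a median of 0.32 (random range -0.14 to 0.14). The estrogen receptor gene Esr2 was 1.91-fold higher, the inhibin and activin subunit genes Inhbb 1.77-fold and Inhba 1.60-fold, and Bmpr1b 1.63-fold. Stroma and fibroblast genes had a median of 0.29 (-0.15 to 0.12), with the transcription factor gene Tcf21 2.76-fold higher (its other measured probe set gave 1.15 on the log2 scale) and the matrix gene Lum 1.79-fold higher. The oocyte list had a median of 0.11 (percentile 76.3) with 0 of 22 members 2-fold apart, and the gene farthest from equality was Nlrp5, 1.48-fold higher. Endothelial genes had a median of 0.25 (percentile 96.7, upper random bound 0.26), with the receptor gene Tie1 1.94-fold and the angiopoietin gene Angpt2 1.92-fold higher. Over the alternatives this median ran from 0.19 without the loess trend to 0.39 without probe sets that can match several transcripts. Theca, luteal and smooth muscle lists had medians of -0.06, -0.11 and 0.05, at percentiles 33.0, 24.7 and 65.4, and the mean of the luteal list was -0.42. The signs of these medians and of the steroid synthesis median turned under at least 1 of the 3 rescalings. Within them the hedgehog-binding protein gene Hhip was 2.57-fold lower by its brightest of 4 measured probe sets, which ranged from -1.36 to -0.28 on the log2 scale, and under 2-fold with the 70th-percentile floor, the offset and the mean over probe sets. The hedgehog receptor gene Ptch1 was 1.97-fold higher and the cell cycle regulator gene Rgcc 1.81-fold lower.

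Among markers of other cells that an ovary sample can hold, Krt7, Krt8, Krt18, Fabp4 and Tppp3 were at least 2-fold apart. Surface epithelium markers had a median of -0.27 (random range -0.14 to 0.32), and 3 of 12 were at least 2-fold lower: Krt7 (3.15-fold), Krt8 (2.26-fold, with probe sets from -1.32 to -0.73 on the log2 scale) and Krt18 (2.06-fold). Each of these 3 calls was lost under an alternative, Krt7 with the 70th-percentile floor and Krt8 and Krt18 with the offset. Krt19 was 1.53-fold lower. Over the alternatives the median log2 difference of the list ovarian surface epithelium ran from -0.44 without probe sets that can match several transcripts to -0.18 with the offset. Leukocyte markers had a median of -0.14 (percentile 1.17), with 0 of 16 members 2-fold apart, and Tyrobp was 1.80-fold lower and Cd14, close to the floor in the knockout, at least 1.80-fold lower. Over the alternatives the median log2 difference of the list leukocytes ran from -0.24 without the loess trend to -0.09 with the 70th-percentile floor. The oviduct list had 5 of 14 genes above the floor and a median of 0.21 (percentile 70.1), with the dim gene Tppp3 2.06-fold higher, but under 2-fold after any of the 3 rescalings. Of erythrocyte genes 2 were measured, Alas2 at -0.07 and Tal1, which was under the floor in the knockout with signals of 38.3 and 34.9 and for which no size is given. Of adipocyte genes 4 were measured, and the fatty acid-binding protein gene Fabp4 was 4.72-fold lower (its other measured probe set gave -1.07 on the log2 scale) while Cd36 differed by 0.08, with probe sets from -0.60 to 0.08, and Lpl by -0.04 on the log2 scale. Slc36a2 was under the floor in the knockout and at least 1.22-fold lower.

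**Figure D3:**
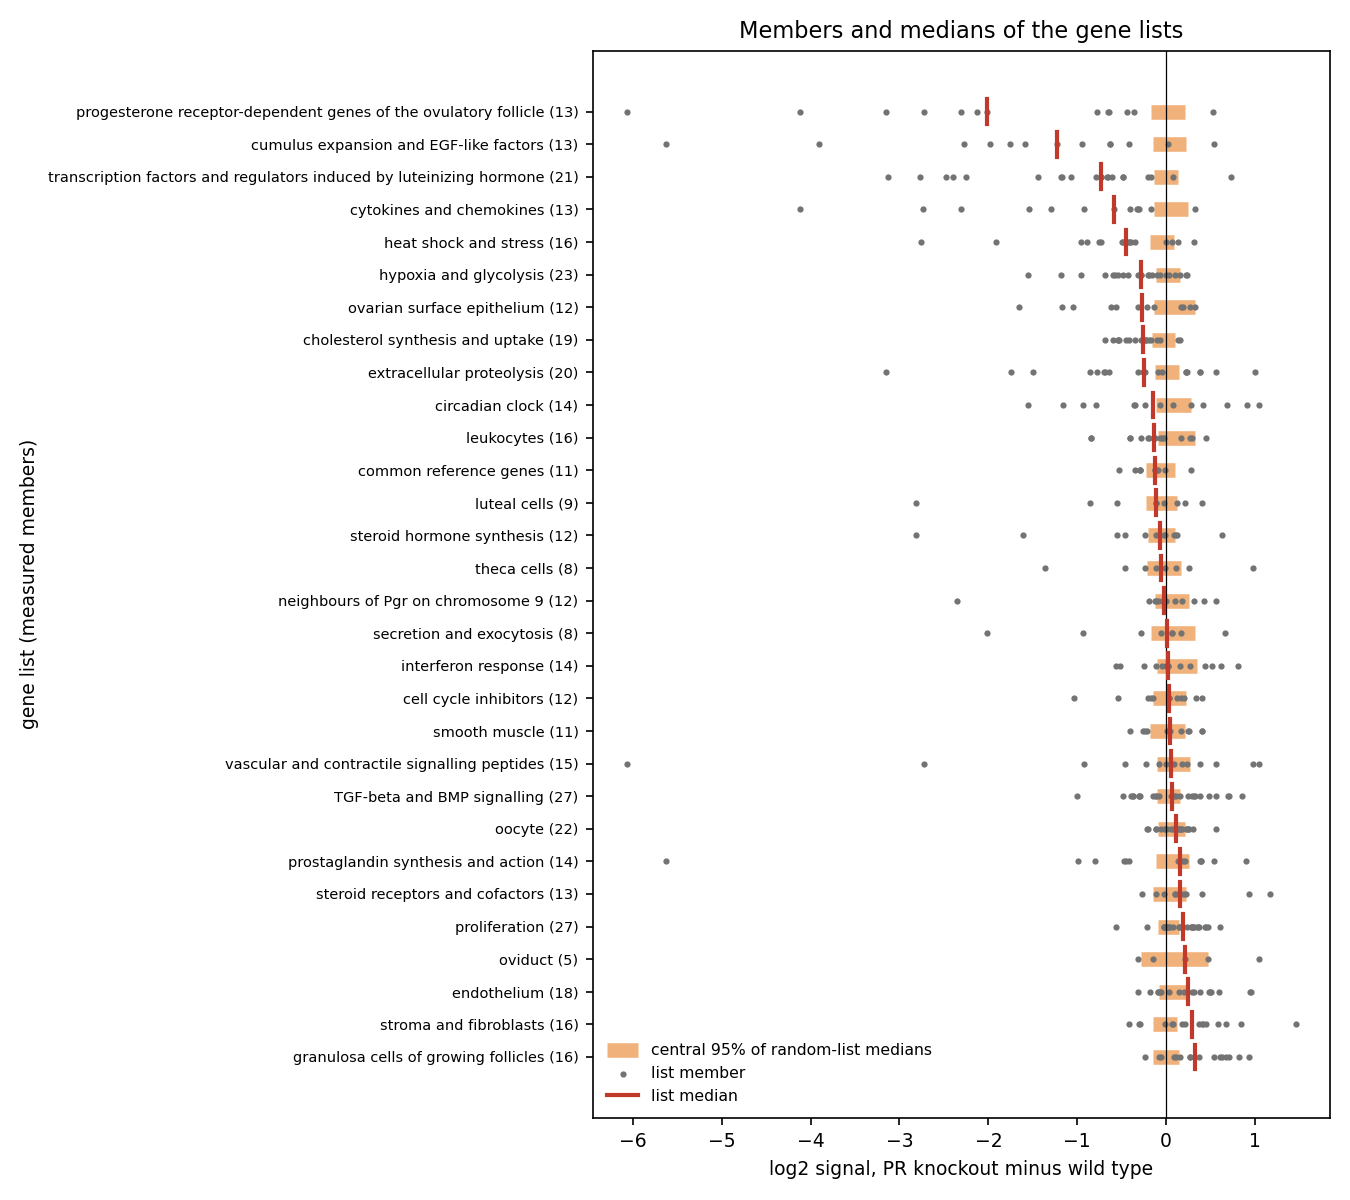
Log2 signal difference, PR knockout minus wild type (horizontal axis), for the measured members (grey points, number in brackets) of 30 gene lists (vertical axis), with each list's median (red line) and the central 95% of medians of 10000 random lists matched on size and mean signal (orange bar). The receptor-dependent, cumulus and luteinizing hormone-induced lists have medians of -2.01, -1.23 and -0.74, outside their bars, and the granulosa and stroma lists lie above theirs at 0.32 and 0.29.

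Signs of RNA quality differed little between the arrays. The beta-actin control probe sets differed by -0.31 at the 3′ end and -0.32 at the 5′ end of the transcript on the log2 scale. The Gapdh control probe sets differed by -0.24 and -0.18. The 3′ and 5′ differences thus lay within 0.06 of each other for both transcripts. The 9 bacterial and phage hybridization spikes, each of which is added in the same amount to both samples, differed by -0.27 to -0.01 with a median of -0.17. Common reference genes had a median of -0.13 (percentile 21.7 among genes of like signal), with Hprt 1.45-fold lower and 10 of 11 members below equality.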

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

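These results come from probe sets outside the gene comparison and were picked because their signal was higher in the knockout than in the wild-type sample, which is the control here. Among 2819 measured probe sets without a gene symbol, 32 were at least 2-fold higher and 54 at least 2-fold lower in the knockout ovary. Among 566 measured probe sets with several gene symbols, 5 were at least 2-fold higher and 3 at least 2-fold lower. The 4 control probe sets for pyruvate carboxylase, an enzyme that feeds the citric acid cycle, were all higher in the knockout, one of them by 1.27 on the log2 scale. The other 3 were higher by between 0.63 and 0.71, and the gene's own probe set (Pcx) by 0.60. None of these differences could be set against a spread between animals.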

How the results depend on the processing

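Counts of genes depended on how dim signals were handled, and list medians mostly did not. In the order higher and then lower in the knockout, the counts of 130 and 195 became 411 and 578 with the floor at the 25th percentile, 35 and 128 at the 70th percentile, 1447 and 1907 with no floor, and 29 and 128 with an offset of 50. At a 1.5-fold threshold in place of 2-fold, the genes at least 2-fold higher in the knockout array became 740 and the genes at least 2-fold lower in the knockout array 538, and at 3-fold 10 and 70. The moves with floor and offset follow from the construction, since more or fewer dim genes can pass, and those with the threshold from a looser or stricter fold. The 3 scalings, the mean over probe sets and the removal of probe sets that can match several transcripts kept both counts within 1.5 times. Of the 130 higher genes, 87 remained under the loess correction, and of the 195 lower genes 192. With the 70th-percentile floor and with the offset, 35 and 28 of the higher genes and 128 and 127 of the lower genes remained. The 61 named genes at least 2-fold apart kept their direction under each alternative that gave them a value. That outcome was close to fixed in advance, since these alternatives can hardly reverse a 2-fold difference. For the largest differences the naming rule also required the same direction in all measured probe sets. Tppp3, Agtr1a and Dbp were under 2-fold after each rescaling, 15 of the 61 with the offset, 6 with the mean over probe sets and 13 of 51 with the 70th-percentile floor. Skida1, Prodh, Rgs13, Abcb10, Il11, Sult1e1, Paqr8, Per2, Id4 and Tppp3 lay under that floor on both arrays and had no value there.

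Of the 14 lists outside their random range, 13 kept the sign of their median under each alternative run. The exception was the median log2 difference of the list circadian clock, which was -0.15 with the brightest probe set and 0.011 with the mean over probe sets. In 8 other cases the value of a list differed from its main median by more than the bootstrap error over members. The median log2 difference of the list progesterone receptor-dependent genes of the ovulatory follicle went to -1.11 with the mean over probe sets, and the cumulus list to -0.64 and the cytokine list to -1.29 with the 70th-percentile floor. Set beside the median log2 difference of the list transcription factors and regulators induced by luteinizing hormone, -0.74, the trimmed mean over its members was -1.03. The leukocyte list went to -0.21 with quantile normalization and -0.24 without the loess trend, the proteolysis list to -0.65 with no floor, and the median log2 difference of the list proliferation to 0.079 without probe sets that can match several transcripts. The lists inside their random range differed in 9 further cases, among them steroid synthesis, whose trimmed mean was -0.27. A trimmed mean is a different statistic, so those cases do not show a median that moved. Which members carried the other moves was not tested. No paired analysis was possible because each genotype has 1 array, and no array could be left out for the same reason. Values of Pgr and of oviduct markers, which lay near or under the floor, are limited by signal over background. The list medians without members shared with the receptor-dependent list were added after the values were seen.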

Other observations

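Several gene groups fixed in advance have not been described above. Of 27 proliferation genes 22 were above equality in the knockout ovary, 0 by 2-fold, with a median of 0.19 (random range -0.09 to 0.15). Without probe sets that can match several transcripts, the median log2 difference of the list proliferation was 0.079, a value inside the range given for the full list. The mitotic kinesin gene Kif20a was 1.52-fold and the spindle gene Tpx2 1.39-fold higher (with probe sets from -0.04 to 0.68 on the log2 scale), while Rrm2, which makes deoxyribonucleotides, was 1.48-fold lower. Cell cycle inhibitors had a median of 0.03 (percentile 45.1) and a mean of -0.07, with Cdkn1a, an inhibitor of cyclin-dependent kinases, 2.05-fold lower, but under 2-fold with the offset or the mean over probe sets. TGF-beta and BMP signalling genes had a median of 0.06 (percentile 69.9), with Id4 2.01-fold lower, although its 3 measured probe sets ranged from -1.01 to -0.03 and it was under 2-fold with the offset or their mean, and the BMP antagonist gene Grem1 1.81-fold higher. Interferon response genes had a median of 0.02 (percentile 18.6), with Ifit2 1.75-fold higher. The signs of the medians of the inhibitor, TGF-beta and interferon lists turned under at least 1 of the 3 rescalings.

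Steroid receptors and their cofactors had a median of 0.16 (percentile 92.0). The membrane progestin receptor gene Paqr8 was 2.24-fold higher in the knockout at dim signals of 46.5 and 104, and its 3 measured probe sets ranged from 0.57 to 1.16 on the log2 scale. It was under 2-fold with the offset or the mean over probe sets. Genes that neighbour Pgr had a median of -0.02 (percentile 17.8) and a mean of -0.11, and 11 of 12 were under 2-fold apart. The exception was the growth factor gene Pdgfd, 5.11-fold lower by its brightest probe set with a log2 difference of -0.43 in its other measured one. Of the sex check genes the X-linked Xist was measured, with a difference of 0.07, and the Y-linked genes with a probe set were under the floor on both arrays. The 4 haemoglobin probe sets, each shared by several globin genes, differed by -0.57 to -0.25.

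The tests of the 3 patterns that follow were chosen after the values were seen, as were the genes singled out for them. The first pattern is the lower signal of the receptor-dependent, cumulus and luteinizing hormone-induced lists. Over 3 rescalings the list median nearest to 0 was -0.72, still below the bound of its random lists. That outcome was close to fixed in advance, so it is no test of scaling. Over 10 bins of mean signal the median difference lay between -0.05 and 0.14. A shift of that size is small beside the 3 list medians and would not account for them. A loss of granulosa cells, in which many of these genes are switched on, would lower granulosa markers too. Their median was 0.32, above the bound of its random lists. This does not decide on such a loss, since the markers are genes of growing follicles. A difference in their level per cell could hide a difference in cell number. A weaker or later response of the knockout sample to hCG cannot be told apart from an effect of the missing receptor, since each genotype has 1 sample. Steroid synthesis genes had a median of -0.069, inside the random range. Set beside the median log2 difference of the list steroid hormone synthesis, the trimmed mean over its members was -0.27. The median was -0.12 after median centring, 0.038 after quantile normalization and 0.005 after removal of the loess trend. The list thus does not decide on a weaker response. An effect of the missing receptor may account for the pattern and stays untested against animal-to-animal spread. A difference between the animals or in the RNA preparation may account for it as well, and coincides with genotype here. The heat shock and stress list moved the same way, with 12 of 16 members lower and a median of -0.45.

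The second pattern is the lower signal of Krt7, Krt8 and Krt18, with a median of -1.18. Krt7 was under 2-fold with the 70th-percentile floor, and Krt8 and Krt18 with the offset. Rescaling left that median at -1.22 or lower. This was close to fixed in advance as well, since median differences over the bins of mean signal, from -0.05 to 0.14, are small beside it. The rescalings are thus no test of a scaling artifact. Fewer surface epithelial cells in the knockout sample cannot be told apart from lower keratin expression per cell. The markers Upk3b, Upk1b, Lgals7 and Msln had a median of 0.013, but 1 of the 4 lay at 3 times the floor or more on both arrays. Brighter members of the list went both ways, with log2 differences of 0.19 for Aldh1a1, 0.27 for Wt1, -0.21 for Aldh1a2 and -0.62 for Krt19. Genotype stays open as well.

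The third pattern is in circadian clock genes, whose list had a median of -0.15 (percentile 0.83) and members on both sides. With the mean over probe sets, the median log2 difference of the list circadian clock turned to 0.011. Bhlhe40 was 2.94-fold, Per2 at least 2.24-fold and Cry1 1.91-fold lower in the knockout, while Dbp was 2.06-fold higher, but under 2-fold after each rescaling. Per2 was under 2-fold with the offset. A different time of day at collection would move 6 genes in phase with Dbp away from 3 genes in antiphase. The gap between their medians was 0.79, above the upper bound of 0.55 for random lists, but the in-phase median rests in part on Ciart, which was under the floor in the wild type, and Per3 was under the floor in the knockout. With the mean over measured probe sets the gap was 0.38, under the bound of 0.52, so the choice of probe set may account for part of it. The time of day at collection is not given in the sources used here, and it and genotype cannot be told apart with 1 sample each.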
